A study of Mus musculus with 6 samples.

How the data were processed

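RNA from mouse embryonic fibroblasts was measured on 6 Affymetrix gene-level arrays, 3 from wild type cells and 3 from cells lacking functional Pax7, which the labels number as biological replicates 1 to 3 in each genotype. Nothing in the labels says which embryos or cultures the numbers stand for, so the p-values of single genes measure the spread between these samples. The deposited values are log2 signals per probe set, made with Partek and RMA (robust multi-array average, which corrects background, normalizes and summarizes probes) per the submitters' processing notes; versions, parameters and a genome build are not given in the sources used here. The log base was read from the range of the values and the name RMA. No further normalization was applied. For arrays, the number of arrays limits the precision, and no depth applies.

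The table held 41345 probe sets without missing values, and 0 pairs of arrays had identical values. The platform annotation gave 1 gene for 23521 probe sets, several for 1814, and did not list 16010. Of the probe sets with 1 gene, 23328 had an Entrez number found in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed through it. Only probe sets with 1 gene were tested. The table holds no detection calls, so a background level was set, after the data were seen, at the 95th percentile of 1390 olfactory and vomeronasal receptor genes on each array (4.63 to 5.44); a gene at or below it on all 3 arrays of a genotype, or in the genotype's mean, is called not above background there, and its difference is given as a lower bound, with the background level in place of a dimmer signal, or not at all. This applied to 27 of the 124 named genes. A gene above background by this rule can still lie below it on single arrays. The tests kept all genes, of which 42.0% to 55.2% lay at or below that level on an array. Where a gene had over 1 probe set (1082 genes), that with the highest mean over all arrays was taken, without regard to genotype, which left 22180 genes. No positions are given because the build of the array is not stated.

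Knockout was compared with wild type with limma (version 3.58.1 in R 4.3.3, lmFit and eBayes, two-sided) with genotype as the only term, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. The SEs printed for genes are limma's, which are drawn toward a spread shared by all genes. They can be smaller or larger than the spread of the 3 pairs alone would give. The test, the gene lists, the rule for named genes and the other settings to be tried were fixed before the data were examined. The rule took Pax7 and, per direction, the 15 largest changes among genes past the threshold without overlap between genotypes, or, with fewer than 5 such genes, the 10 with the smallest unadjusted p and no overlap. It also took up to 4 members of each list past the threshold, or else the 2 with the smallest p, and left out predicted genes without a proper name. After the data were seen, it was repeated in the fit with the replicate block, with a common sign in the 3 pairs in place of no overlap. Genes named outside the rule are said to be so.

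Each of 32 lists, 21 of gene functions and 11 of cell type or sex markers, was compared with all other genes with limma's camera at its preset correlation of 0.01, adjusted over the lists, with the correlation estimated from the arrays as an alternative and limma's fry beside it. At the preset correlation the p-values of lists rest on the spread over genes, taken as nearly independent. They do not measure how far a shift repeats between arrays. The functional lists covered myogenic regulators, skeletal muscle structure, cyclins of the G1/S transition with their kinases and E2Fs, CDK inhibitors with p53 targets, DNA replication, mitosis, fibroblast extracellular matrix, contractile genes, the IGF axis, other growth factors, the Wnt and TGF-beta pathways, interferon and inflammatory genes, Hox genes, neural crest factors, cholesterol synthesis, hypoxia, protein stress, pluripotency and the genes beside Pax7. The marker lists covered neural, epithelial, endothelial, macrophage, erythroid, cartilage, bone, fat, pericyte and mesothelial cells and the sex of the embryo. List members without a usable probe set, among them Trp53, Gadd45a and Bax, were not analysed here.

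Because the genotypes share replicate numbers, it was checked, before calls were compared, whether equal numbers deviate together from their genotype's mean. The deviations of equal-numbered arrays correlated at 0.875, 0.834 and 0.959 for replicates 1, 2 and 3, all above the 0.1 set as the bound, so the number was also fitted as a block and its values are given where they change a call. The pairing comes from the data, not from a label. It rests on replicate 3: arrays of replicate 1 and replicate 2 of opposite genotype also correlated, at 0.835 and 0.860, and the difference between replicates 1 and 2 correlated at only 0.04 between the genotypes. A block with replicates 1 and 2 as 1 batch and replicate 3 as the other was therefore added after the data were seen.

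The fits were tested on simulated data with the real gene means, the real difference of replicate 3 and 200 changed genes among 22180. Without a block, 0% of the genes changed 1.5, 2 or 3 times were called. With the replicate block, 97.0% of those changed 1.5 times and 100% of those changed 2 or 3 times were called, and 21 of the 219 calls were unchanged genes. A list shifted by -0.2 in the simulation had an adjusted p (camera) of 0.00854 without and 2.54e-11 with the block, and 1 other list passed in each. The simulated noise was drawn independently for each gene and array. The simulation therefore cannot show how the preset correlation fares when the members of a list vary together. Its noise had the spread of the blocked fit itself, and replicates 1 and 2 had a common mean. The shares called with the block thus do not show how complete the calls in the data are. In the data Eln, at -1.04, did not pass with the block (limma adjusted p = 0.101). Alternatives were quantile normalization, median centring, filters on dim genes, the mean over probe sets, single probe sets, a trended robust prior, array weights, other thresholds, both blocks and leaving out arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.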

Results

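Gene expression was measured in mouse embryonic fibroblasts (MEFs), primary connective tissue cells cultured from embryos, from wild type mice and from mice lacking functional Pax7, on an F1 background of C57Bl6N and 129Sv. The titles and the design name these cells, while the cell type label of the samples reads ESCs (embryonic stem cells). On every array the fibroblast matrix genes had a median between the 97.7th and the 98.8th percentile of genes and the pluripotency genes one between the 39.2nd and the 52.8th, a comparison chosen after the conflict was seen. The cells were collected at confluence, and each genotype had 3 arrays. Pax7 is a paired-box transcription factor of muscle stem cells and of parts of the embryonic nervous system, and the comparison asks how its absence alters expression in fibroblasts, including genes of the cell cycle. Values are log2 signals, and differences are knockout minus wild type.

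With the replicate number as a block, 15 genes fell and 2 rose in the knockout, and 98, 2 and 4 genes passed without replicates 1, 2 and 3. Among those that fell were secreted and matrix proteins of fibroblasts: Dcn, the proteoglycan decorin, fell by 1.93 on the log2 scale (SE 0.12, 3.81-fold), and Penk, the precursor of enkephalin peptides, fell by 1.55 (SE 0.10, 2.92-fold). Genes of the fibroblast matrix and of mitosis were lower as groups, by medians of -0.20 and -0.18 (limma's camera, adjusted p = 5.74e-14 and 0.00449). Both calls were lost with an estimated correlation (adjusted p = 0.941 for both). Without a block that correlation was 0.698 for the matrix and 0.977 for mitosis. It then takes in the replicate 3 difference, and no list passed. With the block it was 0.06 and 0.11, and both calls were lost as well (camera, adjusted p = 0.702). Without wild type replicate 3 the medians of matrix and mitosis were -0.04 and 0.33, but this leaves the genotypes with unequal shares of replicate 3. With the block and without replicate 3 of both genotypes they were -0.23 and -0.15. Mdm2, the ubiquitin ligase that restrains p53, rose by 0.81 (SE 0.10, 1.75-fold). Without the block, limma called 0 of 22180 genes, and 15 had an unadjusted p under 0.05, 2 higher and 13 lower.

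The arrays separated first by replicate. Both replicate 3 arrays stood apart from the other 4: they correlated at 0.988 with each other, the other 4 at 0.982 to 0.987 among themselves, and arrays across this divide at 0.789 to 0.824. Their interquartile ranges of log2 signal were 2.52 and 2.56, against 1.88 to 1.94 on the other 4. The first principal component held 91.9% of the variance and followed this divide. The second held 2.49%, and on it the wild type arrays lay at 7.66 to 26.1 and the knockout arrays at -26.8 to -4.98.

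**Figure D1:**
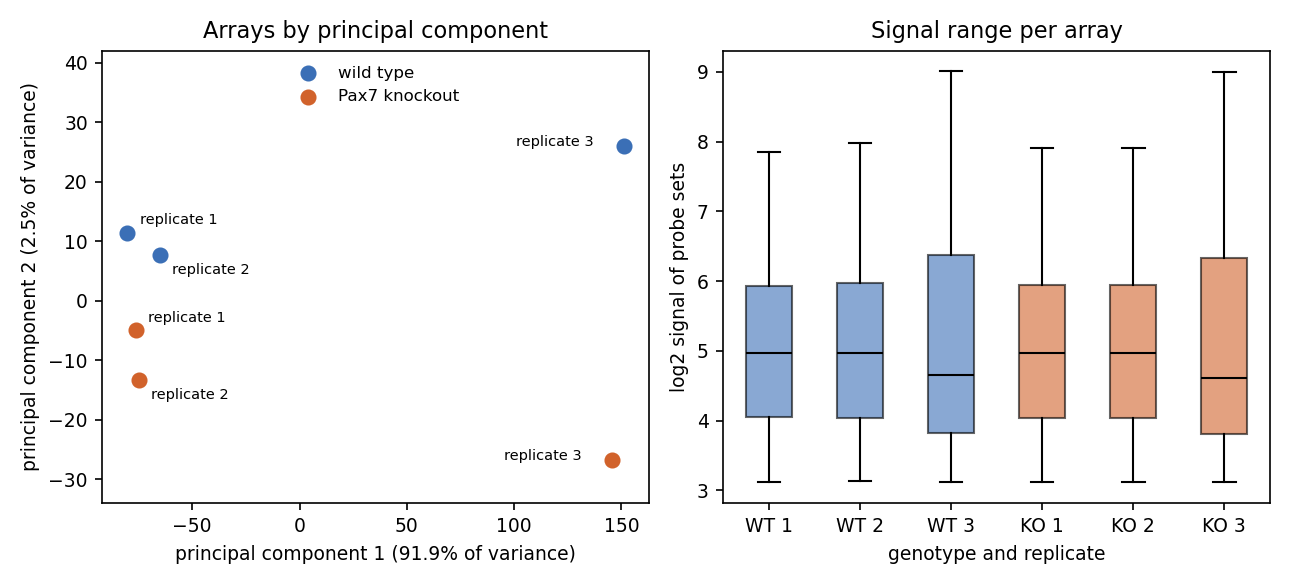
Left, the 6 arrays on the first principal components of all probe sets, including those not tested, with wild type in blue and knockout in orange. Right, log2 signal of all probe sets per array (line, median; box, quartiles; whiskers, 5th and 95th percentiles); the replicate 3 arrays have medians of 4.65 and 4.62, against 4.97 on the others.

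Pax7 had 1 probe set, 17431910, which showed no difference past the threshold. Its log2 signal was 6.14, 5.65 and 4.88 in wild type replicates 1, 2 and 3 and 6.17, 5.95 and 5.05 in the knockout, a difference of 0.16 (SE 0.44; 0.10 with the block; adjusted p = 0.804 with the block). It lay between the 47.4th and the 75.6th percentile of the genes of each array. The background level was 5.44, 5.34 and 4.65 on wild type replicates 1, 2 and 3 and 5.43, 5.34 and 4.63 in the knockout. Pax7 thus lay above it on every array, but near it in wild type replicates 2 and 3. The Pax7 signal was lower on replicate 3 than on replicates 1 and 2 (-1.01), as was the background level. Whether the probe set reads Pax7 transcript in these cells was not tested. Where this probe set lies against the deleted part of the gene is not given in the sources used here, and a probe outside that part does not check the genotype. The genes beside Pax7 on the chromosome had a median difference of -0.00 over 35 members (adjusted p = 0.782), with Mfap2 at -0.25 and Htr6 not above background.

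Apart from Rps13, whose first pair lies at background in both genotypes, the genes past the threshold with the replicate block had the same sign in all 3 pairs. Selection by this fit favours such genes. Besides Dcn (adjusted p = 0.000578) and Penk (0.000578), the growth factor binding proteins Igfbp2 (-0.89, -1.07 and -1.05 in the 3 pairs, limma SE 0.09) and Igfbp3 (-0.73, SE 0.10) fell. So did the imprinted Dlk1, a relative of Notch ligands (-0.95, SE 0.10), the matricellular protein Ccn3 (-0.94, SE 0.11), the heparin-binding growth factor Ptn (-0.68, SE 0.09), the secreted C1qtnf3 (-0.96, SE 0.11), the basement membrane chain Lama4 (-0.80, SE 0.09) and the cadherin Fat4 (-0.77, SE 0.09). Genes of the membrane or metabolism that fell were Plpp1, a lipid phosphatase (-1.02, SE 0.13), Cyb5r3, a cytochrome b5 reductase (-0.92, SE 0.11), the interleukin-1 receptor Il1r1 (-0.81, SE 0.09) and the water channel Aqp1 (-0.79, SE 0.10). Rps13, a protein of the small ribosomal subunit, passed as lower with a knockout signal not above background (mean 3.61, against 6.67 in wild type), so that its fall is given only as at least 1.53 on the log2 scale. This bound rests on wild type replicate 3: it is 0.60 without that array and 0.34 without replicate 3 of both genotypes (2.28 without wild type replicate 1, whose own signal is not above background, and 2.43 without replicate 1 of both). Of the 3 other probe sets that name Rps13, along with other genes, 1 was above background, at 0.85 (1.89, 0.36 and 0.30 in the 3 pairs). Mdm2 and Ttc9 (0.69, SE 0.09) rose. The largest adjusted p of the 17 genes was 0.0400. With the block, leaving out a replicate number moved none of the 16 values besides Rps13 by over 1.5 times (at most 1.25 times). The genes were picked from these same pairs for differences large against their spread. Small moves and a common sign are therefore no separate support for them. Without a block, leaving out 1 array gives the genotypes unequal shares of replicate 3, and 12 moved by more without wild type replicate 3: Lama4 to 0.02, Il1r1 to -0.09, Fat4 to -0.28, Igfbp3 to -0.33, C1qtnf3 to -0.38, Ptn to -0.40, Aqp1 to -0.42, Ccn3 to -0.45, Plpp1 to -0.52, Igfbp2 to -0.64, Ttc9 to 1.07 and Mdm2 to 1.23. Without knockout replicate 3, 7 did so (Lama4 -1.55, Il1r1 -1.49, Fat4 -1.26, C1qtnf3 -1.50, Plpp1 -1.58, Ttc9 0.32, Mdm2 0.41), as did Il1r1 (-0.36) and Lama4 (-0.37) without knockout replicate 1, Lama4 (-0.47) and Plpp1 (-0.68) without knockout replicate 2, and Lama4 and Il1r1 (both -1.22) without wild type replicate 1.

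**Figure D2:**
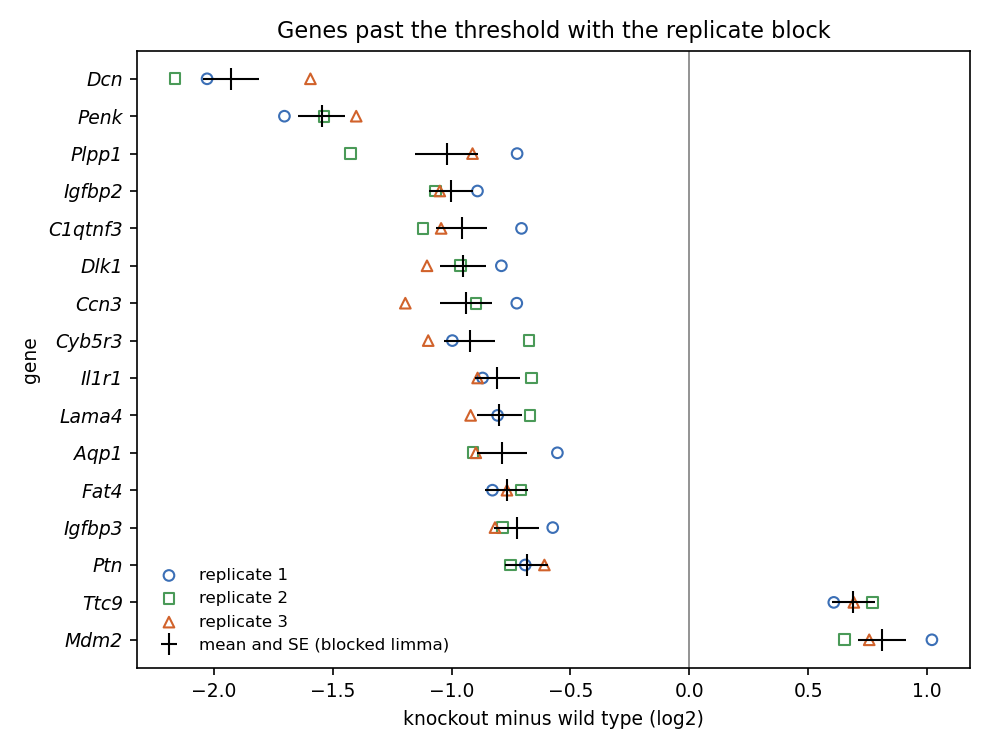
Knockout minus wild type (log2) for genes past the threshold with the replicate block, without Rps13, whose knockout signal is not above background; open symbols are the 3 pairs, and the bar is the blocked mean with its SE. Every pair lies on the same side of 0 as its mean, from -2.16 for Dcn to 1.02 for Mdm2, which the choice of genes by this fit favours.

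These calls depended on the block and on the pairs. With replicates 1 and 2 as 1 batch and replicate 3 as the other, 19 genes passed (2 higher, 17 lower), 16 of them shared with the 17. Within replicates 1 and 2 alone, without a block, 1 gene passed, Dcn (-2.10, SE 0.11, limma adjusted p = 0.00137); the replicate 3 batch holds 1 array per genotype and allows no test. With the block and without replicate 3, 4 genes passed (Dcn, Penk, Rps13 and Igfbp2), without replicate 2 there were 2 (Dcn and Penk), and without replicate 1 there were 98, including all 17.

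Without a block, the genes with the smallest p and no overlap between genotypes, none of them past the threshold (smallest adjusted p = 1.00), were lower for Dlk1, Rps13, Penk, Dcn, Cyb5r3, the microRNA gene Mir337, Cthrc1 (-0.83, SE 0.28), Timp3 (-0.47, SE 0.17), Cdsn (-0.43, SE 0.16) and Cdkn1c (-0.49, SE 0.18). Higher values were found for Fblim1 (0.48, SE 0.15), D5Ertd605e (0.61), Mogat2 (0.49), Ckb (0.44), Snx10 (0.35), Gfod1 (0.37), Cox7c, Olfr353, Lamtor3-ps and Pnp2. No size is given for Mir337, Cox7c, Olfr353, Lamtor3-ps and Pnp2, which were not above background in 1 or both genotypes. In all, 313 genes (1.41%) had no overlap between genotypes. Chance gives 10% for exchangeable arrays, which does not apply here because 1 of the 2 replicate 3 arrays lies in each genotype: the 5 other splits with such an array on each side gave 234 to 306 genes. A total of 6106 genes (27.5%) had 1 sign in the 3 pairs, where chance gives 25%. The higher genes next in order with the block, not past the threshold, were Ppbp (0.87, adjusted p = 0.0578), Anxa1 (0.65, adjusted p = 0.0604), Cd151 (0.55), Specc1 (0.56), Htr2a (0.53), Fosb (0.64), Serinc2 (0.59) and Mcpt8 (0.73). Mcpt8 lay below background in wild type replicates 1 and 2 and knockout replicate 1, so its value rests mostly on the replicate 3 pair (1.07).

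Genes of the fibroblast extracellular matrix were lower as a list, with a median of -0.20 (SD over 28 members 0.45; limma's camera, adjusted p = 5.74e-14; 6.37e-12 with the block). The call was lost with an estimated correlation (adjusted p = 0.941; 0.702 with the block). Of the members, 19 were lower and 3 higher in all 3 pairs. With the block, 1 member (Dcn) passed over all genes, and 14 passed adjusted over the list alone, all of them lower; without it, 0 did. Elastin, Eln, was at -1.04 (SE 0.17 with the block, 0.48 without), with -0.66, -0.78 and -1.67 in the 3 pairs. A further 2 members, chosen after their values were seen, were the collagen VI chain Col6a3 (-0.62, SE 0.09) and the matricellular Postn (-0.43, SE 0.09). Col1a1, a chain of collagen I, chosen in the same way, was at -0.06 (SE 0.09). The call was also lost without wild type replicate 3 (median -0.04, adjusted p = 0.292), and the median was -0.08 without knockout replicate 1 and -0.08 without knockout replicate 2, -0.35 and -0.31 without wild type replicates 1 and 2, and -0.51 without knockout replicate 3. With the block and without replicates 1, 2 and 3 it was -0.16, -0.19 and -0.23 (largest adjusted p = 1.29e-08).

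Genes of mitosis were lower by a median of -0.18 (SD over 27 members 0.11; camera, adjusted p = 0.00449; 2.69e-09 with the block), with pair medians of -0.11, -0.20 and -0.22. This call, too, was lost with an estimated correlation (adjusted p = 0.941; 0.702 with the block). Of the members, 15 were lower and 0 higher in all 3 pairs. None passed over all genes, and with the block 1 passed adjusted over the list alone, the mitotic kinase Plk1 (-0.49, SE 0.11). Aurkb, the kinase of the chromosomal passenger complex, was at -0.31 (SE 0.11 with the block, 0.45 without). Ube2c, which serves the anaphase-promoting complex, was at -0.18 (SE 0.09 with the block, 0.20 without). Without wild type replicate 3 the median was 0.33 (adjusted p = 0.00362), without knockout replicate 1 it was 0.08 (0.596) and without knockout replicate 2 it was 0.08 (0.713); without wild type replicates 1 and 2 and knockout replicate 3 it was -0.48, -0.43 and -0.72. Leaving out 1 array gives the genotypes unequal shares of replicate 3. With the block and without replicates 1, 2 and 3 the median was -0.22, -0.17 and -0.15 (largest adjusted p = 1.25e-05).

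The list of CDK inhibitors and p53 targets had a median of 0.12 over 21 members, with an adjusted p of 0.0841 without the block and 0.0497 with it (adjusted p = 0.702 with the block and an estimated correlation). The blocked call was lost without replicate 1 (median 0.11, adjusted p = 0.116), without replicate 2 (median 0.14, adjusted p just above 0.05) and with the batch block (median 0.12, adjusted p = 0.0554); without replicate 3 the median itself was smaller (0.06, adjusted p = 0.391). Without a block, the median was -0.04 without wild type replicate 1, -0.10 without wild type replicate 2 and -0.22 without knockout replicate 3, and 0.31, 0.23 and 0.23 without wild type replicate 3 and knockout replicates 1 and 2 (adjusted p = 0.000503, 0.00322 and 0.00119). Over this list alone with the block 1 member passed as higher, Mdm2, and 1 as lower, Cdkn1c, the CDK inhibitor p57 (-0.49, SE 0.09), so its called members went opposite ways. Cyclins, kinases and E2Fs of the G1/S transition had a median of 0.03 (21 members, adjusted p = 0.782), with Ccne1 at 0.33, Ccna2 at -0.26 and Cdk6 at 0.42 (SE 0.09 with the block). Cdk6 lay just below background in wild type replicates 1 and 2. Genes of DNA replication had a median of -0.04 (27 members, adjusted p = 0.594; 0.210 with the block), with 7 lower and 3 higher in all 3 pairs and Mcm5 at -0.30, Rfc5 at -0.29 and Fen1 at -0.13.

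The IGF axis was lower by a median of -0.08 over 15 members (camera, adjusted p = 0.0150), which was lost with the replicate block (adjusted p = 0.0580) and with an estimated correlation (adjusted p = 0.941) but not with the batch block (adjusted p = 0.0439). Its members past the threshold with the block were Igfbp2 and Igfbp3, both of which bind IGFs outside the cell. Its pair medians were 0.14, -0.11 and -0.19. Without a block, its median was 0.32 without wild type replicate 3, 0.04 without knockout replicate 1 and 0.11 without knockout replicate 2, none past the threshold (adjusted p = 0.108, 0.793 and 0.713), and -0.33, -0.18 and -0.43 without wild type replicates 1 and 2 and knockout replicate 3. With the block it was -0.09 without replicate 1, where it passed (adjusted p = 0.000373), -0.06 without replicate 2 and 0.02 without replicate 3. The mesothelium and organ mesenchyme markers had a median of -0.08 over 14 members (camera, adjusted p = 0.0150). Osr1 was at -0.62 (SE 0.09 with the block) and Hand2 at -0.22. The list's adjusted p was 0.124 with the block and 0.941 with an estimated correlation. This call was lost without wild type replicates 1, 2 and 3 (medians -0.08, -0.06 and -0.25; adjusted p = 0.160, 0.131 and 0.0981) and without knockout replicate 3 (-0.05; 0.622); without knockout replicates 1 and 2 the median was -0.13 and -0.16.

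**Figure D3:**
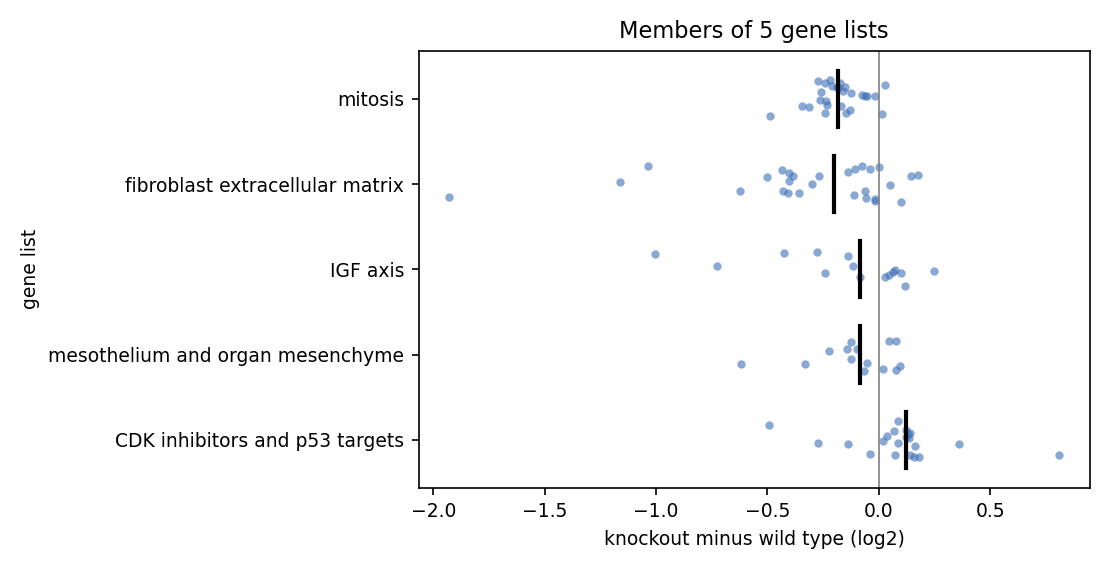
Knockout minus wild type (log2) for each measured member (points) of the 5 lists past the threshold without or with the replicate block; black lines are medians, from -0.20 for the fibroblast matrix to 0.12 for CDK inhibitors and p53 targets.

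No other list passed in either fit. Myogenic regulators had a median of 0.03 (21 members), with Mef2c at -0.25, Itm2a at -0.28 and Msc at 0.21. Skeletal muscle structure genes had a median of 0.05 (25 members), with Acta1 at 0.27 (-0.04, 0.14 and 0.70 in the 3 pairs) and Ryr1 at 0.26. Meox2, Actc1 and Ckm were not above background in 1 or both genotypes. Among signalling lists, FGF, PDGF, HGF and VEGF genes had a median of -0.07, with Fgfr2 at -0.60, Vegfd at -0.71, Spry1 at -0.46 and Fgf2 at 0.21. Fgfr2 lay below background in knockout replicates 1 and 2. Wnt genes had a median of -0.03, with the secreted inhibitors Sfrp1 at -0.58 and Sfrp2 at -0.78 (-0.37, -0.53 and -1.44 in the 3 pairs). TGF-beta and BMP genes had a median of -0.08, with Fst at -0.48, Bmp4 at -0.37 and Inhba at 0.34. Contractile genes had a median of -0.03, with Itga8 at -0.66, Lmod1 at -0.28 and Des at 0.31 (0.07, 0.12 and 0.73 in the 3 pairs). Interferon genes had a median of -0.06, with Ifit1 at -0.29 and Ifit3 at 0.24, and inflammatory and secreted factors one of -0.03, with Cxcl14 at -0.58 and Timp3 at -0.47.

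Hox genes had a median of 0.06 over 36 members (adjusted p = 0.0542), with Hoxb7 at 0.22, Hoxa4 at 0.21 and Hoxb5 at 0.22. Neural crest and craniofacial factors had a median of 0.05, with Twist2 at 0.56 and Prrx1 at -0.42 and Tfap2b not above background in the knockout. Twist2 lay below background in wild type replicates 1 and 2. In the same list Msx2 was at 0.47 (0.20, 0.23 and 0.98 in the 3 pairs). Cholesterol synthesis had a median of 0.03 (Mvd 0.13, Stard4 -0.38, Msmo1 0.21). Stard4 lay below background in replicates 1 and 2 of both genotypes, so its value rests on the replicate 3 pair (-0.66). Hypoxia and glycolysis had a median of 0.03 (Ndrg1 -0.31, Gapdh 0.13, with Egln3 not above background in wild type). Medians were -0.06 for protein and amino acid stress (Chac1 -0.27, Trib3 -0.11, Dnajb9 0.36, Atf3 0.24) and -0.06 for pluripotency genes (Klf2 -0.11, with Dppa5a and Tcl1 not above background in either genotype).

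Markers of cell types other than fibroblasts gave these medians beside the matrix, mitosis and IGF values: neural and glial 0.05 (Nes 0.45, Stmn2 0.48), epithelial 0.03 (Pkp1 0.26, Sfn -0.10, Krt19 0.14), endothelial 0.05, macrophage and blood -0.01, erythroid -0.03, cartilage -0.00 (Matn3 -0.14, Col9a3 0.21), bone -0.13 (Pth1r 0.26, Mepe -0.15, Col10a1 -0.28), fat -0.09 (Cebpa 0.24) and pericyte and smooth muscle 0.03 (Abcc9 -0.30, Des 0.31). Of the markers chosen by the same rule, Emcn, Esam, Lyz2, Mrc1, Hba-x, Gata1, Hapln1, Ebf2 and Lpl were not above background in either genotype and Klf1 not in the knockout, so they have no size here. Stmn2 lay below background in replicates 1 and 2 of both genotypes, so its value rests on the replicate 3 pair (0.95). Des rests mostly on that pair as well (0.73, against 0.07 and 0.12). The sex marker list had a median of 0.05 over 4 members (Xist -0.25; Uty and Eif2s3y not above background in either genotype). Xist, the RNA of the inactive X chromosome, lay between the 98.7th and the 99.3rd percentile of genes on every array, and the Y-linked Eif2s3y between the 0.550th and the 18.0th.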

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

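The count of 0 genes without a block held under quantile normalization, median centring, both filters on dim genes, the mean over probe sets, single probe sets, the trended robust prior, a fold minimum of 1.5, an adjusted p under 0.1 and without each array. It rose to 8 (1 higher, 7 lower) at an unadjusted p under 0.05 with that fold, to 6 with array weights, whose estimate did not converge, and to 17 with the replicate block. Chosen after seeing the data were the batch block (19), replicates 1 and 2 alone (1) and the replicate block with each pair's trend removed (20), quantile normalization (21), genes above the median level (32), the mean over probe sets (16) or a trended robust prior (46). Of the 17 genes, 17, 13, 17, 16 and 16 remained in these last 5. Also chosen then was leaving out each replicate number with the block; over all fits without an array or a number, the count ran from 0 to 98. In the simulation, the fit without a block called 0% of genes changed 3 times, so its count of 0 does not show that genes were unaltered.

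Against 4 lists, 0 passed with an estimated correlation, 0 with fry, 0 with the replicate block and an estimated correlation, 2 in replicates 1 and 2 alone, and 2 to 14 without an array or a number. Elsewhere 3 to 5 passed. List medians over those fits were -0.72 to 0.33 for mitosis, -0.43 to 0.32 for the IGF axis, -0.22 to 0.31 for CDK inhibitors and p53 targets, -0.51 to -0.0401 for the fibroblast matrix and -0.25 to -0.0346 for mesothelium, and each of these calls was lost without at least 1 array or number. The IGF median was 0.016 in replicates 1 and 2 alone. The Pax7 difference ran from -0.17 to 0.50. The replicate block moved no other call of the lists or Pax7 than those given with the results.

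Of 123 named genes besides Pax7, 41 turned sign without an array or a number, of which 21 without wild type replicate 3 and 18 without knockout replicate 3, which leaves the genotypes with unequal shares of the replicate 3 arrays. Their ranges were Lama4 (-1.55 to 0.0166), Cd151 (-0.0224 to 1.12), Itm2a (-0.85 to 0.26), Msc (-0.24 to 0.67), Ryr1 (-0.18 to 0.60), Ccne1 (-0.019 to 0.72), Ccna2 (-0.69 to 0.20), Cdk6 (-0.35 to 1.24), Mcm5 (-0.64 to 0.0451), Fen1 (-0.28 to 0.10), Rfc5 (-0.82 to 0.25), Lmod1 (-0.63 to 0.0543), Vegfd (-1.15 to 0.0331), Fgfr2 (-1.34 to 0.14), Inhba (-0.0258 to 0.61), Bmp4 (-0.86 to 0.12), Hoxb7 (-0.00174 to 0.37), Twist2 (-0.26 to 1.52), Stard4 (-0.96 to 0.35), Msmo1 (-0.18 to 0.66), Egln3 (-0.21 to 0.59), Dnajb9 (-0.63 to 1.27), Atf3 (-0.13 to 0.59), Dppa5a (-0.45 to 0.0434), Tcl1 (-0.45 to 0.0308), Mfap2 (-0.61 to 0.0335), Pla2g5 (-0.17 to 0.60), Nes (-0.0654 to 0.88), Stmn2 (-0.25 to 0.97), Sfn (-0.23 to 0.00879), Krt19 (-0.0711 to 0.39), Klf1 (-0.33 to 0.0141), Hba-x (-0.24 to 0.0435), Gata1 (-0.0942 to 0.28), Matn3 (-0.38 to 0.0351), Col9a3 (-0.54 to 0.83), Col10a1 (-0.76 to 0.31), Cebpa (-0.25 to 0.63), Xist (-0.53 to 0.0592), Uty (-0.0049 to 0.17) and Eif2s3y (-0.23 to 0.42). Of these, Lama4 is among the 17 genes, and Dppa5a, Tcl1, Pla2g5, Egln3, Klf1, Hba-x, Gata1, Uty and Eif2s3y were not above background in 1 or both genotypes, so that their signs carry no weight. In other settings 5 turned: with array weights Actc1 (-0.0396), Fen1 (0.11), Trib3 (0.0871), Htr6 (-0.0029), Eif2s3y (-0.20); with the mean over probe sets, without and with the block, Fen1 (0.0317); and in replicates 1 and 2 alone Fen1 (0.0146) and Eif2s3y (-0.015). With the block, Fen1 (0.0146) and Eif2s3y (-0.0150) turned without replicate 3, Sfn (0.000335) without replicate 2 and Matn3 (0.00773) without replicate 1. Leaving out any 1 array makes the shares of replicate 3 unequal, so that the replicate 3 difference enters the value. The cause of the turns in the other settings was not tested.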

Other observations

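Biology outside the fixed lists came from genes next to the threshold with the block, all chosen after their values were seen. The imprinted gene Mest, an alpha/beta hydrolase of embryonic mesoderm, was at -0.99 (SE 0.14, limma adjusted p = 0.0556 with the replicate block) and passed with the batch block (adjusted p = 0.0490). So did Gas6, the ligand of TAM receptor kinases (-0.62, SE 0.08), and Fbn2, the fibrillin of fetal microfibrils (-0.68, SE 0.09). The 17824 probe sets with several genes or none listed gave 0 calls with the block, and 46 had an unadjusted p under 0.05 without it.

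All tests in this part were chosen after the result they concern was seen, except the counts over other splits of the arrays. The 6 arrays make 10 splits of 3 against 3, and the 3 pairs 4 splits that part every pair, too few for a share under 0.05. Without a block the real split gave 0 genes and the highest other 0, so that 10 of 10 gave as many. With the replicate block the real split gave 17 genes and the highest of the other 3 gave 0, so that 1 of 4 gave as many. For lists without a block the real split gave 4 and the highest other 18, and 7 of 10 gave as many. The 4 splits with both replicate 3 arrays on one side gave 15 to 18 lists and 2768 to 6380 genes with an unadjusted p under 0.05 (15 in the real split), which points to the structure of the samples, and with the block the real split gave 3 lists and another gave 5.

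The replicate 3 arrays stood apart in both genotypes. A narrower signal range on the other 4 arrays, if alike for all genes, would keep their order. As the whole difference it is argued against by rank correlations of at most 0.847 across the divide, against 0.984 to 0.987 among the other 4 arrays and 0.988 between the replicate 3 arrays; a range that differs between genes or probes was not tested. Another set of cell types in replicate 3 could not be excluded. The highest of 10 marker lists, macrophage and blood, lay at percentile 56.1 of 10000 level-matched random lists, and the lowest, cartilage, at 0.04 (median -0.97). The others lay at 7.23 to 30.03, so nearly all lists were on the low side. The background level itself was lower on replicate 3 (4.63 and 4.65, against 5.34 to 5.44). The test may therefore lean toward low values for dim markers, and it settles neither an added type nor a loss. A difference in batch or processing stays open as well, since the labels give neither. The median log2 signal was 4.97 on each of the other 4 arrays and 4.65 and 4.62 on the replicate 3 arrays. The deposited values thus do not share 1 distribution, and the fit without a block pools them as they are. Whether the replicate 3 arrays were normalized apart from the others was not tested.

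The 17 genes called with the block were set against a technical and a biological explanation. For a gradient of signal range within the pairs, each pair's linear trend on the replicate 3 difference was removed, and 17 of the 17 remained past the threshold. The removal moved the values little, such as Dcn from -1.93 to -1.91 and Lama4 from -0.80 to -0.77. A linear trend alike for all genes thus accounts for little of these values. A gradient that is not linear, or that differs between genes, was not tested. A loss or gain of another cell type stays open. No marker list passed camera with the block and an estimated correlation (smallest adjusted p = 0.702). Medians of members above the median level departed from 0 by over 1 standard error for neural (0.15), endothelial (0.13), bone (-0.19) and fat (-0.13) markers. That standard error is one of a mean over 4 to 8 genes, not over arrays, so these departures do not decide it. Types outside the lists were not tested. The effect of the genotype itself stays among the open explanations, as do differences between embryos or cultures, which the labels do not give.

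The difference of Rps13, whose knockout signal was not above background, may belong to its probe set. Of the 3 other probe sets that name Rps13, each shared with other genes such as the pseudogene Rps13-ps4, 2 were not above background. Of these, that shared with Snord14a lay above it on the replicate 3 arrays alone (6.50 in wild type, 6.44 in the knockout), a difference of -0.05. The third had a mean difference of 0.85, from 1.89, 0.36 and 0.30 in pairs 1, 2 and 3. In the replicate 3 pair neither fell as the called probe set did (-4.53). Both also read other genes, so this does not settle it. A fall of ribosomal protein genes as a class is argued against by the median of -0.0117 over the other 66 (SD 0.12, from -0.37 to 0.46). A copy or strain variant under the probes was not tested, and since the other probe sets also read other genes, whether the transcript itself fell stays open.

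The fall of Dlk1 and the low values of Cdkn1c, Mest and Peg3 (-0.59, SE 0.09), none of these last 3 past the threshold with the replicate block, raised the hypothesis that genes of the imprinted growth network may fall together. A list of 18 such genes was written after these values were seen, and 17 were measured. With the 4 genes included, limma's camera with the block gave an adjusted p of 7.64e-06 over 33 lists (0.684 with an estimated correlation), but the 4 genes were what raised the hypothesis, so that this test is circular. Over the 13 other genes the median was -0.06, with 5 lower and 3 higher in all 3 pairs, and the adjusted p was 0.195 at the preset correlation; with an estimated correlation the unadjusted p was 0.184. The other members therefore did not bear the hypothesis out, and the data do not decide it.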
